A study of Mus musculus with 31 samples.

How the data were processed

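Gene expression was measured by RNA-seq of polyA RNA from flash-frozen livers of male C57BL6/J mice. Per the labels, the mice carried 1 of 3 genotypes, named Rosa26KO, Trp53KO and PTENKO, and were 7 or 24 months old. All animals share 1 date of death, and all animals of an age share 1 date of birth. The labels also give each animal a knockout percentage. How it was measured, and how the knockouts were delivered, is not given in the sources used here. Of the 31 samples in the series, 30 were analysed, 5 in each of the 6 groups of age and genotype. The remaining library, of the old PTENKO group, was not used here because no column of the count table used here carries its number. Libraries are named by their group and the library number in the labels. A library is 1 mouse liver.

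Libraries were made with a Watchmaker mRNA kit and sequenced as paired reads on an AVITI instrument, per the labels' protocols. STAR and HOMER, with the mouse builds named GRCm38 and mm10, appear in the submitters' processing notes, without versions or settings. The gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The values are raw counts per gene symbol as deposited: whole numbers, not normalized, in 1 table of 24537 genes and 30 libraries. Every column name holds the library number of 1 sample, and columns were matched to samples by that number. No other processing by the authors enters the values used here. Because the strand setting is unknown, reads from a gene and from an overlapping gene on the other strand cannot be told apart. Members of near-identical gene families can share reads, among them the Cyp3a41 genes with Cyp3a16, the Cyp4a and Cyp2c genes, Gstp1 with Gstp2, Mt1 with Mt2 and the Serpina1 genes. Values of single members of these families are uncertain for that reason.

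Total counts ran from 13796781 to 21390494 per library. Of the 24537 genes, 5290 had no count in any library, and 13888 passed the low-count filter of edgeR (filterByExpr with the 6 groups). The filtered counts were scaled with TMM factors. One negative binomial model with a mean per group was fitted to all 30 libraries, and contrasts were tested with edgeR's quasi-likelihood F test with robust estimation. P values were adjusted by the Benjamini-Hochberg method over the 13888 genes, and a gene was called changed at an adjusted p under 0.05. The 11 comparisons were old against young within each genotype, each knockout against Rosa26KO at each age and averaged over both ages, and the interaction of age with each knockout. Groups shared 1 estimate of the spread in each gene, with a common coefficient of biological variation of 0.21. Fold changes are log2 values from this fit, printed as the value ± its standard error. Levels are CPM, counts scaled by the library size with the TMM factor, printed as the mean ± SD over the 5 libraries of a group. Both knockouts and both interactions were set against the same Rosa26KO libraries, so these comparisons share their chance values, and no overlap between them is reported.

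Before the data were examined, 37 gene lists were fixed: pathways of liver metabolism, stress responses and inflammation, sets of sex-biased and zonated liver genes, and markers of the other cell types a liver can hold. Each list was tested in each comparison with camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists. The median log2 change of a list's measured members is printed with it. Each call was repeated with camera's estimated correlation and with fry, a rotation test of whether a list's genes move one way on balance. A list score per library is the mean over its members of the log2 CPM, with each gene centred over the 30 libraries. Single values, such as a target gene's CPM or the knockout percentage, were compared by exact two-sided permutation tests over all 252 splits of 10 libraries into 5 and 5. Such a test cannot go below 0.00794.

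Named genes were chosen by a rule fixed before the data were examined. It takes Trp53 and Pten in every comparison. It then takes up to 10 genes per direction with the largest called fold change, a mean of at least 2 CPM, an informative symbol and no overlap between the compared groups' libraries. Averages require no overlap at either age, and interactions take 5 genes per direction without that condition. Last, it takes up to 4 called members with the smallest adjusted p from each list that was called or had at least 3 called members. The text gives a selection of these genes. Between groups of 5, a gene shows no overlap by chance in 0.79% of cases.

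Alternatives fixed before the data were examined were RLE size factors, no low-count filter, a mean of at least 5 CPM, the knockout percentage within each group as a covariate, a fold minimum of 1.2, only the compared groups in the fit, DESeq2, limma voom with quality weights, and leaving out each library in turn. Scaling to library size alone, fits without the old libraries 2435 and 2460 together, fits without library 2435 in comparisons that do not use it, the overlap of age changes without it, and the knockout percentage with library 2436 were added after the data were seen. The tests were tried on counts simulated from old against young Rosa26KO, with 200 of 13888 genes changed. At a fold of 1.5, 2 and 4, edgeR recovered 50.7%, 92.5% and 97% of these, with 5 false calls (DESeq2 19, limma voom 7). Real libraries such as 2435 need not follow these rates. Camera called 0 of 50 random lists, which do not test related genes.

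Gene positions come from the GENCODE annotation of the mouse GRCm38 build and were used to place the named genes. Of the 24537 symbols in the table, 23828 are in that annotation. Of the 182 genes in the selection, 181 were placed, and 41 have an exon that overlaps an exon of another gene, among them Dbp (with Sphk2), Igtp (Irgm2), Hadha (Garem2), Kif20a (Cdc23) and Gls2 (Spryd4). Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scipy 1.17.1.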

Results

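Liver gene expression was measured in 30 male mice that carried 1 of 3 knockouts at 7 or 24 months of age. The Trp53KO group carried a knockout of Trp53, which encodes the tumour suppressor p53, and the PTENKO group 1 of Pten, a phosphatase that restrains insulin and growth factor signalling. The Rosa26KO group, edited at a locus commonly used as a neutral site, served as the control. Each of the 6 groups of age and genotype held 5 libraries, 1 per animal. The Rosa26KO and PTENKO libraries share a run of numbers from 2421 to 2441, whereas the Trp53KO libraries are numbered apart, from 2442 to 2460. A processing batch that follows the numbers therefore cannot be told apart from the Trp53KO genotype. It does not follow age, because young and old libraries alternate within both runs.

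Trp53 transcripts were reduced in young Trp53KO livers, and the difference in old livers was not called. Trp53 lies on chromosome 11 at 69580359 to 69591873 of GRCm38, on the plus strand, with 7 exons after merging of its transcripts. Its level was 30.2 ± 2.84 CPM (SD, n = 5) in young Rosa26KO and 14.6 ± 0.985 CPM in young Trp53KO, and each of the 5 knockout libraries (at most 16.3 CPM) lay below each control (27.3 to 33.9 CPM; exact permutation p = 0.00794). In old mice it was 28.8 ± 6.45 CPM in Rosa26KO and 23.3 ± 4.11 CPM in Trp53KO, a difference within the spread of the libraries (exact permutation p = 0.167). One control library set this spread. The library labelled old Rosa26KO 2435 held 17.7 CPM, between the young and old Trp53KO libraries and below the 30.2 to 34.5 CPM of the other 4 old Rosa26KO libraries, so its Trp53 level goes against its label. With it left out, edgeR gave a Trp53 log2 change in old Trp53KO against old Rosa26KO of -0.44 ± 0.11 (SE, adjusted p = 0.0034), in place of -0.30 ± 0.14 (adjusted p = 0.103), which became -0.09 with scaling to library size (adjusted p = 0.674). Within Trp53KO, Trp53 rose with age by 0.67 ± 0.14 on the log2 scale (adjusted p = 0.000628), with old libraries at 19.0 to 27.3 CPM. The knockout percentages in the labels fell alongside, from 37.0 ± 4.64% in young to 26.8 ± 3.03% in old Trp53KO (SD, n = 5, exact permutation p = 0.00794, and 0.0238 adjusted over the 3 genotypes). They were 19.2 ± 3.27% and 19.8 ± 8.11% in young and old Rosa26KO (exact permutation p = 0.929) and 24.6 ± 3.36% and 22.0 ± 5.15% in young and old PTENKO (exact permutation p = 0.405). With the animal that has no counts (2436, 5%) old PTENKO had 19.2% (exact permutation p = 0.221). Trp53 was not called in PTENKO livers against Rosa26KO, with 33.8 ± 4.47 CPM in young and 31.6 ± 4.21 CPM in old mice and log2 changes of 0.16 ± 0.13 and 0.14 ± 0.13 (adjusted p = 0.386 and 0.594), but with scaling to library size it was called higher in young PTENKO (0.39, adjusted p = 0.0331) and over both ages (0.33, adjusted p = 0.0127).

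Pten fell in the PTENKO livers at both ages. It lies on chromosome 19 at 32757497 to 32826160, on the plus strand, with 9 exons after merging. Its level was 110 ± 14.4 and 120 ± 18.5 CPM in young and old Rosa26KO and 41.7 ± 1.71 and 46.5 ± 8.10 CPM in young and old PTENKO (SD, n = 5, exact permutation p = 0.00794 at each age). No PTENKO library exceeded 55.0 CPM, and no Rosa26KO library lay below 87.5 CPM. Pten was also lower in old Trp53KO (81.8 ± 12.0 CPM) than in young Trp53KO (121 ± 6.60 CPM), a log2 change of -0.56 ± 0.12 (adjusted p = 0.000656) that was -0.31 with scaling to library size (adjusted p = 0.0131). Gt(ROSA)26Sor, the transcript of the control locus on chromosome 6 at 113067428 to 113077333, on the minus strand, had an exon that overlaps Thumpd3 on the other strand. It stood at 6.93 ± 1.96 CPM in young Rosa26KO and 7.05 ± 1.65 CPM in young Trp53KO, at 7.15 ± 0.611 and 11.2 ± 2.79 CPM in the old ones, and at 8.08 ± 1.03 and 8.43 ± 1.77 CPM in young and old PTENKO. The position of the edits is not given in the sources used here, and counts over a whole gene include transcripts that carry an edit.

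**Figure D1:**
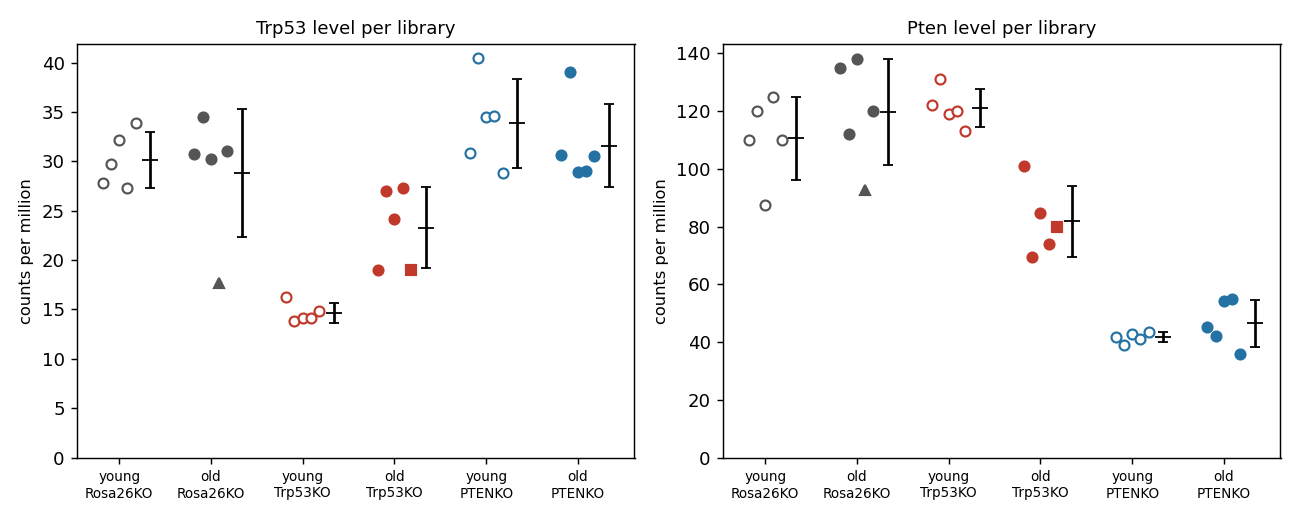
CPM of Trp53 and Pten in each of the 30 libraries, by group (open circles young, filled circles old, dash and bars the mean and SD, n = 5). The library labelled old Rosa26KO 2435 (triangle) sits at 17.7 CPM for Trp53, among the Trp53KO libraries, and library 2460 of old Trp53KO is drawn as a square.

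In young livers, Trp53KO had lower p53 target genes and other levels of clock genes than Rosa26KO. Cdkn1a, a cell cycle inhibitor and classical p53 target on chromosome 17 at 29090976 to 29100727, fell from 43.5 ± 6.73 CPM to 2.31 ± 1.15 CPM, a log2 change of -4.23 ± 0.49 (adjusted p = 1.26e-05). Eda2r, a receptor of the TNF receptor family, fell by 3.93 ± 0.43, and the stress-induced cytokine gene Gdf15 fell by 2.45 ± 0.39. The p53 targets Aen (an exonuclease) and Phlda3 changed by -0.96 ± 0.11 and -1.56 ± 0.31. Of 35 measured p53 target genes, 10 fell and 0 rose (14 lower adjusted over the list alone). Their median log2 change was -0.35 (camera adjusted p = 1.25e-15), and the call held with adjusted p = 0.000448 with an estimated correlation. Among 19 circadian clock genes, 12 rose and 4 fell (13 and 5 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 7.08e-09, and adjusted p = 0.00677 with an estimated correlation). Dbp, a clock-controlled transcription factor whose exons overlap those of Sphk2 on the other strand, rose from 3.91 ± 1.57 to 97.5 ± 16.4 CPM. Bhlhe41 rose by 3.93 ± 0.61, Per3 by 3.43 ± 0.59 and Bhlhe40 by 1.45 ± 0.23, all of them clock repressors, while Npas2, a partner of the clock activator Bmal1, fell by 2.89 ± 0.54.

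Genes of the interferon response and of the NRF2 antioxidant programme were also lower in young Trp53KO. Among 40 interferon response genes, 11 fell and 0 rose (20 lower adjusted over the list alone), with a median of -0.62 (camera adjusted p = 7.81e-18, and adjusted p = 0.156 with an estimated correlation). The antiviral gene Rsad2 fell from 77.0 ± 13.9 to 18.1 ± 5.86 CPM, and its neighbour Cmpk2 from 56.1 ± 8.61 to 16.4 ± 4.98 CPM. Of 20 NRF2 targets, 6 fell and 0 rose (15 lower adjusted over the list alone), among them the epoxide hydrolase gene Ephx1 (-1.01 ± 0.17). The list median was -0.82 (camera adjusted p = 9.34e-13, and adjusted p = 0.0522 with an estimated correlation). Of 24 genes of the unfolded protein and integrated stress response, 3 fell and 0 rose (6 lower and 1 higher adjusted over the list alone), including the endoplasmic reticulum chaperone gene Creld2 (-1.08 ± 0.22). That list had a median of -0.33 (camera adjusted p = 0.00332, and adjusted p = 0.517 with an estimated correlation). In all, 184 genes rose and 226 fell among 13888, 410 together. The count was 1177 without the library labelled old Rosa26KO 2435, which is not in this comparison but enters the shared spread, and 1483 with only the compared groups in the fit. It was 169 without young Rosa26KO 2421, 239 without 2425 and 220 without 2429, and 225, 209, 205 and 231 without young Trp53KO 2442, 2446, 2450 and 2454.

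In old livers, Trp53KO had lower fatty acid oxidation genes and higher B cell, neutrophil and inflammatory genes than Rosa26KO. Hadhb and Hadha, which encode the mitochondrial trifunctional protein, fell by 0.66 ± 0.10 and 0.76 ± 0.14, and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, fell from 236 ± 45.3 to 128 ± 29.6 CPM. Of 23 fatty acid oxidation genes, 15 fell and 0 rose (18 lower adjusted over the list alone), with a median of -0.55 (camera adjusted p = 3.19e-09, and adjusted p = 0.253 with an estimated correlation) that was -0.34 with scaling to library size. The B cell gene Cd19 rose from 1.54 ± 0.930 to 7.20 ± 2.84 CPM, and 13 of 17 B and plasma cell markers rose with none falling (15 adjusted over the list alone, median 1.47, camera adjusted p = 1.59e-08, and adjusted p = 0.255 with an estimated correlation). Of 6 neutrophil markers, 5 rose (6 adjusted over the list alone, median 1.49, camera adjusted p = 3.09e-05, and adjusted p = 0.253 with an estimated correlation), including the neutrophil receptor gene Csf3r (1.37 ± 0.20). The p53 targets Eda2r, Cdkn1a and Aen remained lower, by 2.99 ± 0.42, 2.02 ± 0.42 and 1.11 ± 0.11, with Cdkn1a at -3.16 without libraries 2435 and 2460. Of the 35 p53 target genes, 13 fell and 1 rose, the same numbers adjusted over the list alone, and the median was -0.10 (camera adjusted p = 0.00725, and adjusted p = 0.289 with an estimated correlation). Without 1 library that median ranged from -0.18 (old Rosa26KO 2431) to -0.04 (old Trp53KO 2456), with -0.05 without old Rosa26KO 2423 and -0.16 and -0.17 without old Trp53KO 2444 and 2448, and it turned to 0.10 with scaling to library size.

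Inflammatory genes were higher and endothelial genes lower in the same comparison. Hp, the acute phase protein haptoglobin, rose from 2430 ± 294 to 4800 ± 665 CPM, and Saa1, serum amyloid A, from 29.0 ± 13.2 to 77.4 ± 32.1 CPM. Of 25 acute phase genes, 8 rose and 4 fell (10 and 4 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.00572, and adjusted p = 0.476 with an estimated correlation) that was 0.79, 0.28 and 0.25 without the libraries 2435, 2423 and 2460. Of 22 NF-kB targets, 10 rose and 0 fell (12 adjusted over the list alone, median 0.62, camera adjusted p = 2.13e-06, and adjusted p = 0.253 with an estimated correlation), with the chemokine gene Cxcl1 at 1.63 ± 0.40. Of 40 interferon response genes, 16 rose and 0 fell (18 adjusted over the list alone, median 0.44, camera adjusted p = 2.13e-06, and adjusted p = 0.468 with an estimated correlation). Monocyte and macrophage markers rose in 4 of 18 cases and fell in 0 (4 adjusted over the list alone, median 0.58, camera adjusted p = 0.00572, and adjusted p = 0.514 with an estimated correlation), and in 9 of 18 without the library labelled old Rosa26KO 2435, with a median of 1.12. Among 38 cell cycle genes, 16 rose and 0 fell (24 adjusted over the list alone, median 0.92, camera adjusted p = 9.44e-07, and adjusted p = 0.468 with an estimated correlation), for example the kinesin gene Kif20a (0.92 ± 0.23). Of 21 endothelial markers, 10 fell and 0 rose (11 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 2.13e-06, and adjusted p = 0.289 with an estimated correlation), among them the vascular receptor gene Flt1 (-1.16 ± 0.16) and the water channel gene Aqp1 (-0.92 ± 0.13), and with a median of -0.23 with scaling to library size.

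Hepatocyte genes fell in part. The urea cycle gene Cps1 fell by 1.34 ± 0.24 and the apolipoprotein gene Apob by 0.63 ± 0.12, and 7 of 24 hepatocyte identity genes fell while 1 rose, the same numbers adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.00188, and adjusted p = 0.434 with an estimated correlation), -0.13 without old Trp53KO 2456, and -0.01 with scaling to library size. Of 18 bile acid genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone, median -0.53, or -0.32 with scaling to library size, camera adjusted p = 0.00188, and adjusted p = 0.253 with an estimated correlation). In all, 1423 genes rose and 1789 fell among 13888 in old Trp53KO against old Rosa26KO. The direction rests on controls that include the library labelled old Rosa26KO 2435. Leaving it out gave 2635 higher and 2628 lower, with 2812 of the 3212 calls shared, and leaving out old Trp53KO 2456 gave 2123. With only these groups in the fit, 149 genes were called. Scaling to library size took the median of all genes from 0.006 to 0.204 and the share of higher genes among the called from 44.3% to 85.4%.

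Averaged over both ages, Trp53KO livers had lower p53 targets. Eda2r, Cdkn1a and Phlda3 fell by 3.46 ± 0.30, 3.13 ± 0.32 and 1.42 ± 0.22, and Aen, Ccng1 and Trp53inp1 by 1.03 ± 0.08, 0.78 ± 0.11 and 0.89 ± 0.12. Of the 35 p53 target genes, 13 fell and 0 rose (14 adjusted over the list alone, median -0.18, camera adjusted p = 1.19e-13), and the call held with adjusted p = 0.00074 with an estimated correlation. That median was -0.08 with scaling to library size. Of 19 clock genes, 8 rose and 5 fell (12 and 5 adjusted over the list alone, median 0.58, camera adjusted p = 0.00146, and adjusted p = 0.307 with an estimated correlation), with Bhlhe40 at 1.24 ± 0.16 and Npas2 at -2.09 ± 0.36. Trp53 itself fell by 0.68 ± 0.10 (adjusted p = 0.000104). The average called 383 genes higher and 672 lower, 1055 together, and 3022 without the library labelled old Rosa26KO 2435. It called 631, 1602, 701 and 1763 without young Rosa26KO 2421 and 2429, young Trp53KO 2454 and old Trp53KO 2460. Library-size scaling took the median of all genes from -0.005 to 0.102 and the share of higher genes from 36.3% to 84.0%, and 435 genes were called with only these groups in the fit.

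Young PTENKO livers had higher genes of lipid droplets, of extracellular matrix and of the cell cycle than Rosa26KO. Library 2426 stood above the other 4 young PTENKO libraries for matrix and cell cycle genes, by 0.905 and 0.771 of the group's range. Cidec and Cidea, which encode proteins that enlarge lipid droplets, rose from 6.27 ± 3.23 to 162 ± 33.9 CPM and from 0.248 ± 0.25 to 82.6 ± 31.2 CPM. Apoa4, an apolipoprotein made when fat is exported, rose from 242 ± 36.4 to 5030 ± 1650 CPM, a log2 change of 4.38 ± 0.36 (adjusted p = 5.86e-09), and the fatty acid transporter gene Cd36 rose by 1.71 ± 0.17. Of 18 lipid droplet genes, 13 rose and 0 fell, the same numbers adjusted over the list alone, with a median of 1.14 (camera adjusted p = 1.18e-16), and the call held with adjusted p = 0.000385 with an estimated correlation. Of 32 extracellular matrix and fibrosis genes, 27 rose and 0 fell (28 adjusted over the list alone, median 1.47, camera adjusted p = 3.39e-25, and adjusted p = 0.0932 with an estimated correlation). The collagen genes Col1a1 and Col1a2 rose by 3.40 ± 0.41 and 2.59 ± 0.31. Among 38 cell cycle genes, 30 rose and 0 fell (33 adjusted over the list alone, median 1.34, camera adjusted p = 8.12e-13, and adjusted p = 0.266 with an estimated correlation). Of 18 stellate cell and fibroblast markers, 10 rose and 2 fell (14 and 2 adjusted over the list alone, median 0.53, camera adjusted p = 1.88e-05, and adjusted p = 0.266 with an estimated correlation).

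Macrophage markers and genes of fetal liver and liver tumours were higher in young PTENKO, and hepatocyte genes were lower. Of 18 infiltrating monocyte and macrophage markers, 12 rose and 0 fell (13 adjusted over the list alone, median 1.85, camera adjusted p = 6.45e-11, and adjusted p = 0.155 with an estimated correlation). Gpnmb, a gene of lipid-laden macrophages, rose by 5.87 ± 0.74, and the chemokine receptor gene Ccr2 by 2.30 ± 0.33. Of 19 fetal liver and liver tumour genes, 10 rose and 0 fell (11 adjusted over the list alone, median 1.25, camera adjusted p = 7.72e-08, and adjusted p = 0.139 with an estimated correlation), among them Anxa2 (3.16 ± 0.30) and Ly6d (4.77 ± 0.58). Of 26 genes of senescence and its secreted factors, 12 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.76, camera adjusted p = 4.95e-07, and adjusted p = 0.191 with an estimated correlation). Library 2426 stood above the others for these 3 lists too. Of 24 hepatocyte identity genes, 14 fell and 0 rose, the same numbers adjusted over the list alone (median -0.52, camera adjusted p = 3.64e-08, and adjusted p = 0.139 with an estimated correlation), for example Cps1 (-1.21 ± 0.24) and Ahsg (-0.95 ± 0.20), with a list median of -0.30 after scaling to library size.

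Oxidative phosphorylation genes and some interferon genes were lower in young PTENKO. Of 39 oxidative phosphorylation genes, 21 fell and 0 rose (27 adjusted over the list alone, median -0.30, camera adjusted p = 4.69e-08, and adjusted p = 0.376 with an estimated correlation), with a median of -0.08 after scaling to library size. Among 40 interferon response genes, 8 fell and 0 rose (7 adjusted over the list alone, median -0.45, camera adjusted p = 0.00047, and adjusted p = 0.516 with an estimated correlation), and of 22 lipogenesis genes, 4 rose and 0 fell (2 adjusted over the list alone, median 0.78, camera adjusted p = 0.00458, and adjusted p = 0.581 with an estimated correlation). Without the library labelled old Rosa26KO 2435 in the shared fit, 16 interferon response genes fell and 2 rose (the list median was -0.23 with scaling to library size), and 14 lipogenesis genes rose and 1 fell. In all, 1926 genes rose and 1682 fell in young PTENKO against young Rosa26KO, 3608 of 13888. Leaving out young PTENKO 2426 gave 2086, and a mean of at least 5 CPM left 2398. Scaling to library size took the median of all genes from -0.017 to 0.207 and the share of higher genes among the called from 53.4% to 90.3%.

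In old livers, PTENKO kept higher lipid droplet genes, collagens and cell cycle genes than Rosa26KO. Cd36 stood at 200 ± 30.7 against 97.0 ± 19.9 CPM, Apoa4 rose by 1.87 ± 0.32, and Plin5, a lipid droplet coat protein, by 0.61 ± 0.11. Of 18 lipid droplet genes, 7 rose and 0 fell (8 adjusted over the list alone, median 0.72, camera adjusted p = 1.1e-09), and the call held with adjusted p = 0.0135 with an estimated correlation. Of 38 cell cycle genes, 12 rose and 0 fell (27 adjusted over the list alone, median 0.90, camera adjusted p = 1.8e-14, and adjusted p = 0.339 with an estimated correlation). Extracellular matrix and fibrosis genes rose in 5 of 32 cases, including Col1a1 (2.03 ± 0.39), and fell in 0 (11 adjusted over the list alone, median 0.59, camera adjusted p = 6.48e-07, and adjusted p = 0.478 with an estimated correlation). The median was 0.39 without old PTENKO 2424. Of 19 fetal liver and liver tumour genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.61, camera adjusted p = 3.78e-06, and adjusted p = 0.223 with an estimated correlation), with Anxa2 at 2.12 ± 0.29. NRF2 targets rose in 4 of 20 cases and fell in 0 (11 adjusted over the list alone, median 0.59, camera adjusted p = 4.01e-08, and adjusted p = 0.223 with an estimated correlation), led by the carbonyl reductase gene Cbr3 (3.49 ± 0.72).

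Hepatocyte and fasting genes were lower in old PTENKO. The amino acid catabolism gene Tat fell by 1.46 ± 0.28, and Cps1 fell to 1370 ± 333 CPM. Of 24 hepatocyte identity genes, 7 fell and 0 rose (14 adjusted over the list alone, median -0.43, camera adjusted p = 8.91e-08, and adjusted p = 0.223 with an estimated correlation), and 11 fell without the library labelled old Rosa26KO 2435. Of 16 FOXO and fasting targets, 5 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.55, camera adjusted p = 0.00133, and adjusted p = 0.359 with an estimated correlation), but without that library 2 fell and 1 rose, with a median of -0.28. Its removal also changed Got1, an aminotransferase, from -3.47 ± 0.72 to -0.77 ± 0.23, Igfbp2 from -2.20 ± 0.47 to -1.03 ± 0.29, and Cth from -1.72 ± 0.40 to -0.62 ± 0.19. In all, 465 genes rose and 461 fell, 926 together. Without the library labelled old Rosa26KO 2435 the count was 1232, of which 642 were shared, and without old PTENKO 2424, 2428 and 2441 it was 364, 487 and 569. With only these groups in the fit 89 genes were called, and scaling to library size moved the share of higher genes from 50.2% to 84.3%.

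Averaged over both ages, PTENKO livers combined higher lipid droplet, matrix and cell cycle genes with lower hepatocyte genes. Sprr1a, Ephb2, Rad51b and Themis rose by 7.51 ± 0.70, 4.79 ± 0.30, 3.46 ± 0.30 and 3.36 ± 0.22, and Cidec and Apoa4 by 3.17 ± 0.30 and 3.12 ± 0.24. Of 18 lipid droplet genes, 12 rose and 0 fell (14 adjusted over the list alone, median 0.87, camera adjusted p = 8.14e-20), and the call held with adjusted p = 0.000159 with an estimated correlation. Of 32 matrix and fibrosis genes 26 rose (27 adjusted over the list alone, median 1.02, camera adjusted p = 8.1e-23, and adjusted p = 0.0756 with an estimated correlation), and of 38 cell cycle genes 31 rose (34 adjusted over the list alone, median 1.21, camera adjusted p = 2.48e-19, and adjusted p = 0.161 with an estimated correlation). Of 24 hepatocyte identity genes 16 fell (18 adjusted over the list alone, median -0.43, camera adjusted p = 3.57e-11, and adjusted p = 0.0659 with an estimated correlation), with Cps1 at -1.35 ± 0.17 and a median of -0.28 after scaling to library size, and no member of these last 3 lists moved the other way. Pten fell by 1.39 ± 0.08 (adjusted p = 8.16e-12). The average called 1675 genes higher and 1563 lower, with the library labelled old Rosa26KO 2435 among the controls. Library-size scaling took the median of all genes from -0.020 to 0.148 and the share of higher genes from 51.7% to 90.2%.

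**Figure D2:**
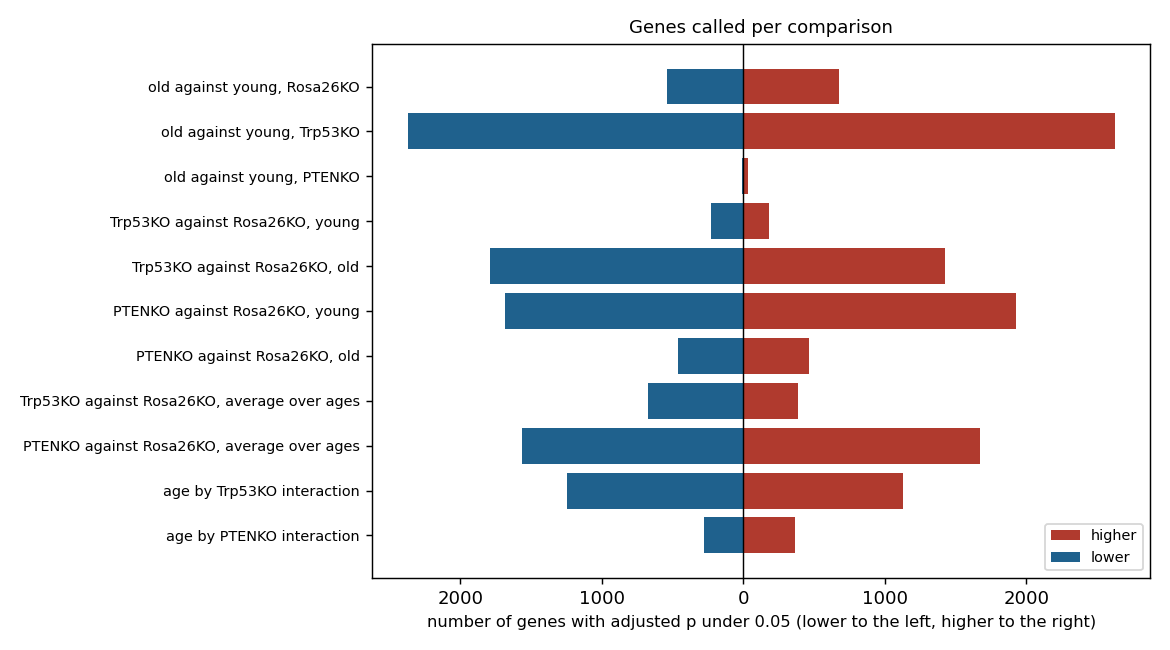
Number of genes called higher (bars to the right of 0) and lower (bars to the left of 0) in each of the 11 comparisons at an adjusted p under 0.05 in edgeR, of 13888 genes tested. Old against young Trp53KO has 2627 higher and 2372 lower genes, and old against young PTENKO has 31 and 12.

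Ageing in Rosa26KO livers lowered antioxidant and respiratory chain genes and raised markers of stromal and immune cells. Gstp1 and Gstm1, which encode glutathione transferases, fell from 3670 ± 1050 to 1070 ± 474 CPM and from 10200 ± 3540 to 3110 ± 2000 CPM. The carbonyl reductase genes Cbr3 and Cbr1 fell by 3.84 ± 0.73 and 1.30 ± 0.22. Of 20 NRF2 targets, 11 fell and 1 rose (13 and 1 adjusted over the list alone, median -0.61, camera adjusted p = 2.85e-09, and adjusted p = 0.244 with an estimated correlation). Of 39 oxidative phosphorylation genes, 19 fell and 0 rose (33 adjusted over the list alone, median -0.32, camera adjusted p = 5.22e-16, and adjusted p = 0.244 with an estimated correlation), for example Ndufs7 (-0.45 ± 0.10). Noct, a clock-linked phosphatase gene, rose from 18.6 ± 9.66 to 124 ± 63.5 CPM, and the lipid droplet genes Cidea and Cidec rose by 5.97 ± 1.08 and 2.09 ± 0.42, while the list of 18 lipid droplet genes was not called (camera adjusted p = 0.0569). The stromal genes Pdgfrb, Dcn and Mmp14 rose by 0.82 ± 0.16, 0.84 ± 0.18 and 1.00 ± 0.19. These genes were still called in a fit without the library labelled old Rosa26KO 2435, in which 6 NRF2 targets and 3 oxidative phosphorylation genes fell, with medians of -0.49 and -0.28.

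Calls of immune and matrix markers with age in Rosa26KO depended on the library labelled old Rosa26KO 2435, whose Trp53 level goes against its label, while their medians kept their direction without it. Of 18 infiltrating monocyte and macrophage markers, 10 rose and 0 fell (15 adjusted over the list alone, median 1.53, camera adjusted p = 5.7e-09, and adjusted p = 0.244 with an estimated correlation), and 3 rose without it, with a median of 1.00. Of 10 MHC class II genes, 8 rose, the same number adjusted over the list alone (median 1.56, camera adjusted p = 1.88e-06, and adjusted p = 0.244 with an estimated correlation), and 1 rose without it, with a median of 1.05. The antigen presentation gene Cd74 changed by 2.20 ± 0.51 with it and by 1.07 ± 0.38 without it (adjusted p = 0.108). For 29 T and NK cell markers, 2 rose (15 adjusted over the list alone, median 1.10, camera adjusted p = 6.24e-05, and adjusted p = 0.518 with an estimated correlation), and 0 did without it, with a median of 0.50. Of 6 neutrophil markers, 3 rose (6 adjusted over the list alone, median 1.48, camera adjusted p = 0.000783, and adjusted p = 0.244 with an estimated correlation), and 0 did without it, with a median of 1.03. Stellate cell and fibroblast markers rose in 6 of 18 cases (10 adjusted over the list alone, median 0.41, camera adjusted p = 1.16e-05, and adjusted p = 0.304 with an estimated correlation), and in 5 without it, with a median of 0.27. Of 32 matrix and fibrosis genes, 6 rose (8 adjusted over the list alone, median 0.46, camera adjusted p = 9.17e-05, and adjusted p = 0.518 with an estimated correlation), and 1 did without it, with a median of 0.36. Male-biased liver genes fell in 2 of 18 cases (6 adjusted over the list alone, median -0.89, camera adjusted p = 1.17e-07, and adjusted p = 0.312 with an estimated correlation), and in 1 without it, with a median of -0.72. Of 40 interferon response genes, 1 rose and 1 fell, the same numbers adjusted over the list alone (median -0.36, camera adjusted p = 1.66e-05, and adjusted p = 0.498 with an estimated correlation), and 0 did without it, with a median of -0.33. The metallothionein genes Mt1 and Mt2 changed by 5.56 and 6.47 with it and by 0.00 and -0.14 without it.

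In all, 677 genes rose and 537 fell with age in Rosa26KO, 1214 of 13888. Without the library labelled old Rosa26KO 2435, 255 rose and 242 fell, and 386 of these 497 genes were also called with it. Without young Rosa26KO 2421, 2425 and 2429 the counts were 296, 626 and 586. Fitted with only the old and young Rosa26KO libraries, edgeR called 5 genes, so the count rests on the spread shared with the other groups. Scaling to library size moved the share of higher genes among the called from 55.8% to 75.1%.

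Ageing in Trp53KO livers raised markers of every leukocyte type listed for B, T, neutrophil and monocyte lineages. The B cell genes Cd79b, Cd19 and Cd22 rose by 2.73 ± 0.32, 2.99 ± 0.46 and 2.10 ± 0.23, and the T cell gene Thy1 by 2.50 ± 0.28. S100a9, an abundant neutrophil protein, rose from 0.458 ± 0.154 to 7.93 ± 3.24 CPM, and Ccr2 rose by 2.47 ± 0.34. Of 17 B and plasma cell markers, 16 rose (16 adjusted over the list alone, median 2.39, camera adjusted p = 1.95e-11, and adjusted p = 0.102 with an estimated correlation). Of 29 T and NK cell markers, 24 rose (25 adjusted over the list alone, median 2.17, camera adjusted p = 4.65e-10, and adjusted p = 0.247 with an estimated correlation). All 6 neutrophil markers rose, also adjusted over the list alone (median 3.10, camera adjusted p = 1.47e-08, and adjusted p = 0.0585 with an estimated correlation). Of 18 infiltrating monocyte and macrophage markers, 16 rose (17 adjusted over the list alone, median 2.18, camera adjusted p = 4.51e-10, and adjusted p = 0.102 with an estimated correlation), and all 10 MHC class II genes did, also adjusted over the list alone (median 1.87, camera adjusted p = 6.66e-08, and adjusted p = 0.102 with an estimated correlation). No member of these lists fell.

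Inflammatory and proliferation genes rose with them. The chemokine gene Ccl2 and the cytokine gene Tnf rose by 3.13 ± 0.43 and 3.34 ± 0.53, and Lcn2, a secreted acute phase protein, from 3.23 ± 0.749 to 102 ± 138 CPM. Of 22 NF-kB targets, 19 rose and 0 fell (20 and 1 adjusted over the list alone, median 1.39, camera adjusted p = 6.14e-12, and adjusted p = 0.066 with an estimated correlation). Among 40 interferon response genes, 30 rose and 0 fell (30 adjusted over the list alone, median 0.78, camera adjusted p = 7.83e-10, and adjusted p = 0.247 with an estimated correlation), including the nucleic acid sensor gene Zbp1 (2.09 ± 0.29). Of 25 acute phase genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone, median 1.04, camera adjusted p = 0.000187, and adjusted p = 0.252 with an estimated correlation), with Hp up from 2010 ± 243 to 4800 ± 665 CPM. Of 38 cell cycle genes, 21 rose and 0 fell (24 adjusted over the list alone, median 1.04, camera adjusted p = 2.37e-05, and adjusted p = 0.475 with an estimated correlation), such as the proliferation marker gene Mki67 (2.16 ± 0.48). Noct rose from 21.3 ± 9.75 to 286 ± 283 CPM.

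Metabolic genes of hepatocytes fell in ageing Trp53KO livers. Hadhb, Etfdh and the carnitine carrier gene Slc25a20 fell by 0.83 ± 0.10, 1.11 ± 0.14 and 0.69 ± 0.09, the last by 0.44 with scaling to library size. Of 23 fatty acid oxidation genes, 18 fell and 1 rose (21 and 1 adjusted over the list alone, median -0.78, camera adjusted p = 1.21e-12, and adjusted p = 0.102 with an estimated correlation). Of 18 male-biased liver genes, 10 fell and 0 rose (11 adjusted over the list alone, median -1.01, camera adjusted p = 1.46e-05, and adjusted p = 0.289 with an estimated correlation), with Cyp2d9 down from 2030 ± 233 to 524 ± 294 CPM. Of 20 xenobiotic metabolism genes, 10 fell and 0 rose (11 adjusted over the list alone, median -0.54, camera adjusted p = 9.42e-05, and adjusted p = 0.102 with an estimated correlation), including Cyp2c29 (-1.76 ± 0.31), and with a median of -0.28 after scaling to library size. Of 24 hepatocyte identity genes, 9 fell and 1 rose, the same numbers adjusted over the list alone (median -0.31, camera adjusted p = 0.000271, and adjusted p = 0.252 with an estimated correlation), with a median of -0.05 after scaling to library size. Of 19 clock genes, 3 fell and 1 rose, also adjusted over the list alone (median -0.50, or -0.22 with scaling to library size, camera adjusted p = 0.0108, and adjusted p = 0.247 with an estimated correlation). Cyp3a41a and Cyp3a16, female-biased cytochromes that can share reads, were called higher (5.20 ± 1.22 and 5.46 ± 1.25) but changed by -0.82 and -0.65 without old Trp53KO 2460 and by -0.22 and -0.13 with limma voom. In all, 2627 genes rose and 2372 fell, 4999 of 13888. Library-size scaling took the median of all genes from 0.032 to 0.290 and the share of higher genes from 52.6% to 87.8%.

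Ageing in PTENKO livers changed few genes. Noct rose from 14.1 ± 4.27 to 129 ± 11.8 CPM, a log2 change of 3.20 ± 0.48 (adjusted p = 0.0013). Of 40 interferon response genes, 2 rose and 0 fell (12 adjusted over the list alone, median 0.49, camera adjusted p = 5.03e-13, and adjusted p = 0.386 with an estimated correlation). They were the GTPase gene Igtp (0.96 ± 0.21), whose exons overlap those of Irgm2, and Irf1 (0.71 ± 0.16), and both lost the call without any 1 of the libraries 2422, 2424, 2426, 2430, 2434, 2438 and 2441, Igtp also without 2432 (adjusted p of 0.0659 to 0.238 for Igtp and 0.082 to 0.238 for Irf1), and both also with scaling to library size (adjusted p = 0.108). Of 32 matrix and fibrosis genes, 1 fell and 0 rose (6 adjusted over the list alone, median -0.48, camera adjusted p = 4.31e-12, and adjusted p = 0.386 with an estimated correlation), and without young PTENKO 2426 the median was -0.23. The gene that fell, Col14a1, lost the call without any 1 of 2426, 2430, 2432, 2434, 2438, 2440 and 2441 (adjusted p of 0.0597 to 0.161) and with scaling to library size (0.0677). Of 18 lipid droplet genes, 2 fell and 0 rose (4 adjusted over the list alone, median -0.49, camera adjusted p = 1.24e-06, and adjusted p = 0.0847 with an estimated correlation). These, Apoa4 and Fitm2, lost the call without any 1 of the same 7 libraries or 2422 (adjusted p of 0.0597 to 0.203), Apoa4 also with scaling to library size (0.0846). Endothelial markers fell in 11 of 21 cases adjusted over the list alone, though in none over all genes (median -0.33, camera adjusted p = 1.11e-11, and adjusted p = 0.179 with an estimated correlation). In all, 31 genes rose and 12 fell, 43 of 13888, with 1729 at an unadjusted p under 0.05. The count was 139 without the library labelled old Rosa26KO 2435 in the shared fit, and 19, 14, 19, 17 and 19 without young PTENKO 2422, 2426, 2430, 2434 and 2438. Without old PTENKO 2428, 2432, 2440 and 2441 it was 81, 18, 28 and 13, and it was 153 with only these groups in the fit.

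The effect of age differed between Trp53KO and Rosa26KO livers in 2378 genes. Interferon genes had positive interactions. Mx1, an antiviral GTPase, had an interaction (the log2 change with age in Trp53KO minus that in Rosa26KO) of 2.52 ± 0.46, and Zbp1 one of 2.02 ± 0.40. Among 40 interferon response genes, 24 had a positive and 0 a negative interaction (31 adjusted over the list alone, median 1.10, camera adjusted p = 2.16e-17, and adjusted p = 0.337 with an estimated correlation). Ly6c2, Thy1, Csf3r and Cd19 had interactions of 2.79 ± 0.51, 1.93 ± 0.39, 1.47 ± 0.30 and 2.83 ± 0.65. Of 17 B and plasma cell markers, 6 were positive and 0 negative (7 adjusted over the list alone, median 1.70, camera adjusted p = 2.79e-06, and adjusted p = 0.337 with an estimated correlation). Fatty acid oxidation genes were negative in 11 of 23 cases and positive in 0 (15 adjusted over the list alone, median -0.65, camera adjusted p = 9.88e-08, and adjusted p = 0.337 with an estimated correlation), among them Etfdh (-1.10 ± 0.20) and Hadhb (-0.78 ± 0.14), and were negative in 18 without the library labelled old Rosa26KO 2435. Of 24 hepatocyte identity genes, 6 were negative and 1 positive (8 and 1 adjusted over the list alone, median -0.36, camera adjusted p = 0.000499, and adjusted p = 0.34 with an estimated correlation), with Cps1 at -1.84 ± 0.33 and a median of -0.18 after scaling to library size. Of 21 endothelial markers, 8 were negative and 0 positive (10 and 1 adjusted over the list alone, median -0.26, camera adjusted p = 0.00136, and adjusted p = 0.432 with an estimated correlation), including Flt1 (-1.26 ± 0.23), and the median was -0.07 after scaling to library size.

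Trp53 itself had an interaction of 0.74 ± 0.19 (adjusted p = 0.0107) and Pten one of -0.68 ± 0.17 (adjusted p = 0.00702). The p53 targets Bax, Mdm2 and Cdkn1a had interactions of 1.12 ± 0.19, 0.73 ± 0.18 and 2.21 ± 0.63, and that of Cdkn1a was 1.29 without old Trp53KO 2460 (adjusted p = 0.0507). Of 35 p53 target genes, 4 were positive and 2 negative (5 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.0308, and adjusted p = 0.376 with an estimated correlation). Removing old Rosa26KO 2423, young Rosa26KO 2433 or old Trp53KO 2460 ended that call (camera adjusted p = 0.052, 0.0566 and 0.086), and scaling to library size took the median to 0.44. Across all genes, 1130 interactions were positive and 1248 negative. With the library labelled old Rosa26KO 2435 left out, 3905 were called, 2258 of them shared, and with young Rosa26KO 2429 left out, 1486. Ciart and Usp2 had interactions of -4.35 ± 1.01 and -3.79 ± 0.84, which became -2.13 and -1.84 without library 2435. Lepr and Cyp3a41b were also called, but Lepr (-4.81 ± 1.35) was -0.96 without library 2435 (adjusted p = 0.142), and Cyp3a41b (5.81 ± 1.67) was -0.27 without old Trp53KO 2460. Scaling to library size took the median of all interactions from 0 to 0.181 and the share of positive ones from 47.5% to 80.5%.

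The effect of age differed between PTENKO and Rosa26KO livers in 648 genes. The lipid droplet genes Cidea, Cidec and Apoa4, higher in young PTENKO, had interactions of -6.45 ± 1.29, -3.02 ± 0.56 and -2.51 ± 0.45. Of 18 lipid droplet genes, 5 were negative and 0 positive (7 adjusted over the list alone, median -0.90, camera adjusted p = 1.32e-05, and adjusted p = 0.198 with an estimated correlation). Of 32 matrix and fibrosis genes, 10 were negative and 0 positive (17 adjusted over the list alone, median -0.93, camera adjusted p = 3.55e-12, and adjusted p = 0.289 with an estimated correlation), and 6 were negative without the library labelled old Rosa26KO 2435. Of 21 endothelial markers, 6 were negative and 0 positive (16 adjusted over the list alone, median -0.56, camera adjusted p = 2.73e-11, and adjusted p = 0.204 with an estimated correlation), and 9 without that library. Of 18 infiltrating monocyte and macrophage markers, 6 were negative and 0 positive (8 adjusted over the list alone, median -1.44, camera adjusted p = 3.02e-06, and adjusted p = 0.335 with an estimated correlation), and 4 without it, with a median of -0.70. Oxidative phosphorylation genes were positive in 12 of 39 cases and negative in 0 (29 adjusted over the list alone, median 0.45, camera adjusted p = 1.79e-13, and adjusted p = 0.289 with an estimated correlation), and interferon response genes in 10 of 40 and 0 (24 adjusted over the list alone, median 0.86, camera adjusted p = 1.76e-13, and adjusted p = 0.289 with an estimated correlation). Cbr3 had an interaction of 3.96 ± 0.94 (adjusted p = 0.0249, and 0.0548 without young Rosa26KO 2421).

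Across all genes, 368 interactions of age with PTENKO were positive and 280 negative. With the library labelled old Rosa26KO 2435 left out 700 were called, 464 of them shared. The count depended on single libraries, with 142, 364 and 226 without young Rosa26KO 2421, 2425 and 2429, 145 and 196 without young PTENKO 2426 and 2434, and 284, 353 and 132 without old PTENKO 2432, 2440 and 2441. Library-size scaling took the median of all interactions from -0.031 to -0.145 and the share of positive ones from 56.8% to 28.7%, and called 390 genes.

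**Figure D3:**
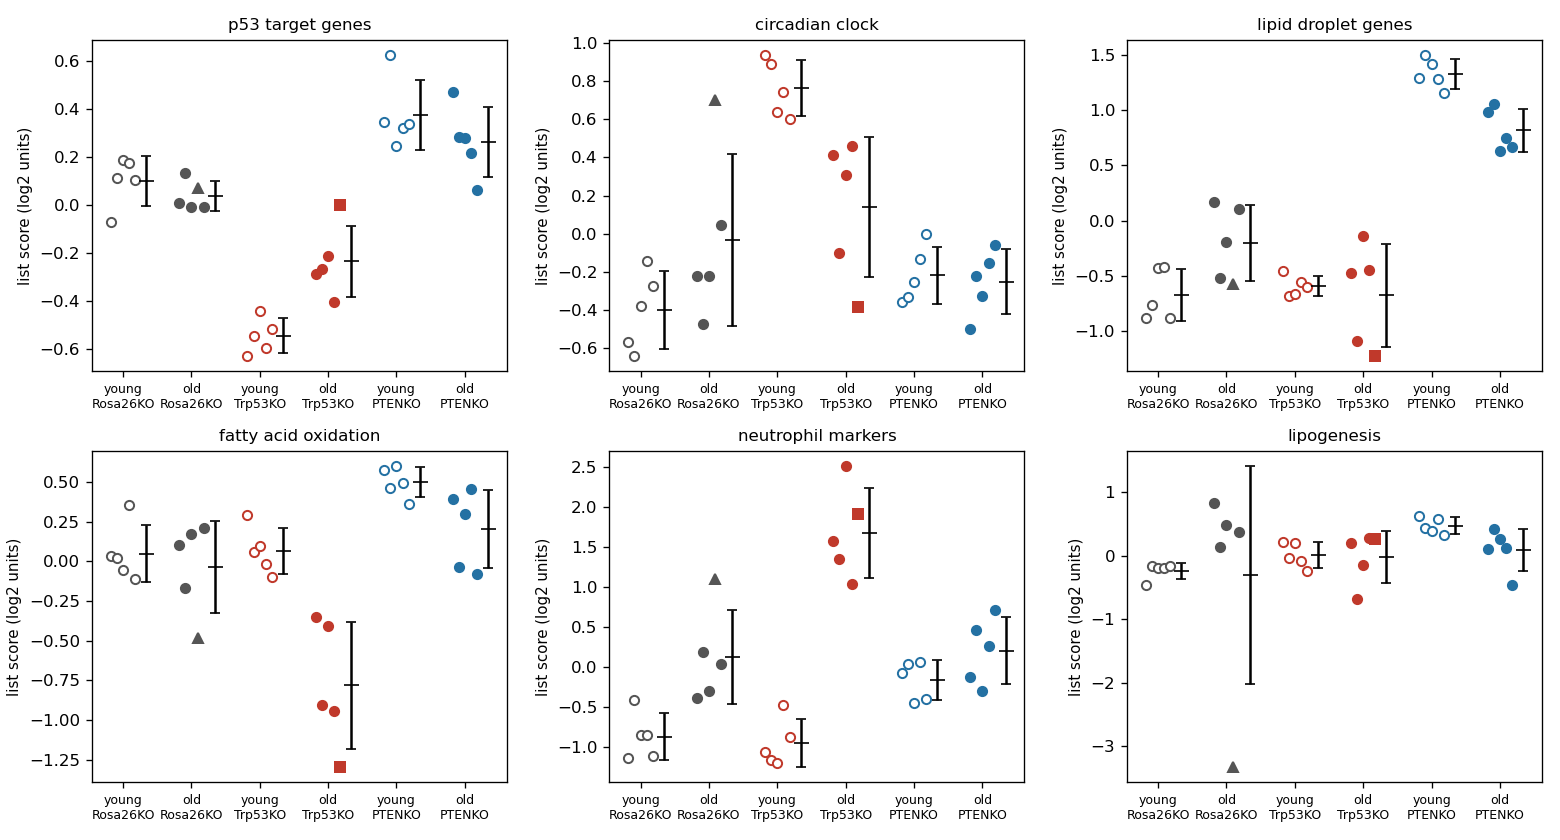
Scores of 6 gene lists (mean centred log2 CPM of the members) in each of the 30 libraries by group, with the mean and SD (n = 5). Old Trp53KO libraries lie low for fatty acid oxidation and high for neutrophil markers, and the library labelled old Rosa26KO 2435 (triangle) and library 2460 (square) are marked.

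Age changes in Rosa26KO and Trp53KO overlapped among the genes that rose. Of the 677 and 2627 genes that rose with age, 286 rose in both, against 128.1 for independent lists (Fisher's exact test p = 5.72e-47, with genes not being independent replicates). Of those that fell, 90 fell in both against 91.7 (Fisher's exact test p = 0.598), and 101 changed in opposite directions. Without the library labelled old Rosa26KO 2435, 113 rose in both against 58.9 (Fisher's exact test p = 3.96e-14), 61 fell in both against 52.8 (p = 0.114), and 61 changed in opposite directions. In Trp53KO and PTENKO, 22 genes rose in both against 5.9 for independent lists and 8 fell in both against 2.0, and 0 changed in opposite directions (50, 39 and 3 without that library in the shared fit). In Rosa26KO and PTENKO, 15 changed the same way and 5 in opposite directions (23 and 3 without it). At an unadjusted p under 0.01 the numbers were 42 and 52, and the changes of all genes had a Spearman correlation of -0.109. Noct was called higher with age in all 3 genotypes. Within genotypes and beside age, the knockout percentage tracked 0 genes in Trp53KO (edgeR, the tool run for this, with 409 genes at an unadjusted p under 0.05 and 658 expected), 7 in PTENKO and 188 in Rosa26KO. The Rosa26KO count was 3561 without old library 2427 and 0 without any 1 of 2421, 2423, 2429, 2431, 2433, 2439 and the library labelled old Rosa26KO 2435, which has the lowest percentage of its group at 10%. The PTENKO count was 611, 162, 13, 3 and 1 without 2441, 2432, 2434, 2422 and 2430, and 0 without any 1 of 2424, 2426, 2428, 2438 and 2440.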

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

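The library splits, interaction tests and leave-out fits were planned before the results were seen. Other tests here were chosen after them, and the measure that decides on a wrong label of 2435 was replaced and extended after its values were seen.

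The library labelled old Rosa26KO 2435 stood apart from the other 4 old Rosa26KO libraries, with 17.7 CPM of Trp53 and a male-biased liver gene score of -3.71 against 0.05 to 0.31. A Trp53KO library under the wrong label cannot be told apart from a true Rosa26KO library here. Of the genes that separate genotypes, 91% lay on the Trp53KO side (0 to 28% in other Rosa26KO and PTENKO, 37 to 97% in Trp53KO). In 2435, the 10-gene p53 score of 3.35 lay with old Trp53KO (at most 3.63), not other old Rosa26KO (4.29 to 4.72). Yet 4 of 10 p53 genes exceeded every Trp53KO library. Its lipogenesis score of -3.33 lay outside the -0.68 to 0.27 of Trp53KO, which a wrong label does not bring. Its 35-gene p53 score was 0.07 (other old Rosa26KO -0.01 to 0.13, Trp53KO -0.63 to 0.00). Its knockout percentage (10%, Trp53KO 24 to 45%) is a label and decides nothing. RNA of other cell types diluting hepatocyte RNA is argued against for the low lipogenesis genes, which fell 3.44 below hepatocyte identity (-3.44, against -0.03 to 0.59 in the other 4), but stays open for the high blood cell markers: erythroid genes scored 1.88 (-0.41 to 0.16) and T and NK cell markers 1.59 (-0.53 to 0.77), with hepatocyte identity at 0.10 (0.16 to 0.32), yet B and plasma cell markers -0.91 (-0.27 to 0.79). A fasted state stays open, because FOXO and fasting targets scored 0.90 (-0.12 to 0.39 in the other 4) while fatty acid oxidation scored -0.48 (-0.17 to 0.21).

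Clock genes differed between young Trp53KO libraries (scores of 0.60 to 0.94) and young Rosa26KO libraries (-0.64 to -0.14). A collection time or batch that follows the Trp53KO numbering cannot be told apart from the genotype, since no Rosa26KO library carries such a number. Loss of Trp53 also stays open: old Trp53KO libraries scored -0.39 to 0.46, with 2460 at -0.39 and 19.0 CPM of Trp53, within or above the -0.47 to 0.05 of the other 4 old Rosa26KO libraries. The library labelled old Rosa26KO 2435, numbered in the other run, scored 0.70.

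Old Trp53KO livers had lower fatty acid oxidation genes and higher leukocyte markers than young ones. A lower share of hepatocytes stays open: incoming leukocytes would dilute endothelium too (endothelial score -0.12, hepatocyte identity -0.39, neutrophil 2.63). Fatty acid oxidation, chosen for its fall, changed by -0.46 relative to hepatocyte identity (exact permutation p = 0.0238), beyond even dilution of hepatocyte RNA. The composition factor of the normalization is argued against by 16 of 18 called fatty acid oxidation genes still being called with scaling to library size. A change within hepatocytes that comes with age when Trp53 is lost remains a hypothesis, as does a change of the leukocytes themselves, and neither was tested apart.

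With 100 splits of the same libraries drawn for each of the 11 counts of called genes, the real split was the largest, 1 of 100, in 9 comparisons, so that chance can be excluded for each of these taken alone, without adjustment over the 11 comparisons. For age, the real counts and the highest of the other splits were 1214 and 74 in Rosa26KO, 4999 and 1972 in Trp53KO, and 43 and 0 in PTENKO. In young mice they were 410 and 1 for Trp53KO and 3608 and 1 for PTENKO, on average over ages 1055 and 537 and 3238 and 8, and for the interactions 2378 and 1811 and 648 and 18. In old mice 3 of 100 splits, the real one included, called as many genes, with 3212 and 4711 for Trp53KO and 926 and 1493 for PTENKO. The split with 4711 exchanges the library labelled old Rosa26KO 2435 with old Trp53KO 2460, and that with 1493 with old PTENKO 2432. This points to a structure of samples around 2435. A swap with 2460 stays open. Its Trp53 (19.0 CPM) lay on the Trp53KO side, as did 37% of separating genes (74 to 97% in other Trp53KO). Its 35-gene p53 score was 0.00 (at most -0.21).

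In 72 of 655 measures of 5 libraries, 1 library lay far from the other 4, by the gap to its neighbour as a share of the range, where chance flags about 1 in 20 groups, or 33. In the library labelled old Rosa26KO 2435 the share was 0.752 for Abhd2, 0.72 for Adgrv1, 0.894 for Asl, 0.906 for Ccng1, 0.775 for Ciart, 0.921 for Cth, 0.75 for Cyp2c29, 0.776 for Cyp4a10, 0.876 for Dcn, 0.904 for Got1, 0.752 for H2-DMb2, 0.847 for Igfbp2, 0.922 for Lepr, 0.713 for Mmp14, 0.848 for Mt1, 0.937 for Mt2, 0.75 for Ndufb3, 0.863 for Npas2, 0.765 for Pla2g7, 0.862 for Ppargc1a, 0.731 for S100a9, 0.842 for Slc22a26, 0.871 for Slco1a4, 0.8 for Trp53, 0.763 for Usp2, 0.778 for Vwf, 0.772 for bile acid genes and 0.937 for male-biased liver genes. For young PTENKO 2426 it was 0.775 for Anxa2, 0.831 for Anxa5, 0.779 for Cdc20, 0.853 for Col1a1, 0.854 for Col1a2, 0.814 for Gls2, 0.887 for Loxl2, 0.825 for Mmp12, 0.894 for Pdgfrb, 0.762 for Plk1, 0.771 for cell cycle, 0.905 for extracellular matrix and fibrosis, 0.725 for fetal liver and liver tumour genes, 0.727 for infiltrating monocyte and macrophage markers and 0.821 for senescence and its secreted factors. For old Trp53KO 2460 it was 0.858 for Cyp3a16, 0.778 for Cyp3a41a, 0.783 for Cyp3a41b and 0.752 for Cyp4a12b. Elsewhere it was 0.833 for Cdkn1a, 0.85 for Col1a2, 0.76 for Gls2 and 0.898 for lipogenesis in young Rosa26KO 2421, 0.918 for Gvin1 in young PTENKO 2422, 0.763 for Plin5 and 0.788 for Tat in old PTENKO 2424, 0.726 for Ciart and 0.918 for Sprr1a in young Rosa26KO 2425, 0.805 for Trp53 in old PTENKO 2428, 0.808 for Etfdh, 0.73 for Mt2 and 0.844 for Serpina1a in young Rosa26KO 2429, 0.738 for extracellular matrix and fibrosis in old Rosa26KO 2431, 0.784 for Noct and 0.729 for total count in old Rosa26KO 2439, 0.744 for Slc22a26 in old PTENKO 2440, 0.721 for Fitm2 and 0.768 for endothelial markers in old PTENKO 2441, 0.744 for Csf3r and 0.727 for knockout percentage in young Trp53KO 2442, 0.882 for Oas2 in old Trp53KO 2444, 0.752 for Noct in old Trp53KO 2448 and 0.776 for Cdkn1a and 0.857 for MHC class II genes in young Trp53KO 2450.

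Age effects differed between genotypes by the interaction test. With Trp53KO, 2378 genes differed, and the log2 interaction, or the median of a list, was 0.74 for Trp53, -0.68 for Pten, 4.27 for Slfn4, 5.81 for Cyp3a41b, -4.35 for Ciart, -3.79 for Usp2, -4.81 for Lepr, -4.49 for Mt1, 1.12 for Bax, 0.73 for Mdm2, 2.21 for Cdkn1a, -1.10 for Etfdh, -0.78 for Hadhb, 2.52 for Mx1, 2.02 for Zbp1, 2.79 for Ly6c2, 1.93 for Thy1, 2.83 for Cd19, 1.47 for Csf3r, -1.84 for Cps1, -1.26 for Flt1, 1.10 for interferon response, -0.65 for fatty acid oxidation, 1.70 for B and plasma cell markers, -0.36 for hepatocyte identity genes, 0.26 for p53 target genes and -0.26 for endothelial markers. With PTENKO, 648 genes differed, with 3.96 for Cbr3, 2.37 for Gsta2, 2.06 for Gvin1, -7.20 for Mt2, -6.45 for Cidea, -5.58 for Lepr, -2.51 for Apoa4, -3.02 for Cidec, -1.14 for Col14a1, -1.08 for Reln, -4.05 for Gpnmb, 1.17 for Psmb8, 1.22 for Mx2, -0.93 for extracellular matrix and fibrosis, 0.86 for interferon response, -0.90 for lipid droplet genes, -0.56 for endothelial markers, 0.45 for oxidative phosphorylation and -1.44 for infiltrating monocyte and macrophage markers. With 1 library left out, some calls were lost. Psmb8 lost its call without any 1 of 2421, 2425, 2426, 2429, 2431, 2432, 2434 and 2441 (adjusted p of 0.0527 to 0.0802) and with library-size scaling (0.0722), and Mt1 with Trp53KO without any 1 young Rosa26KO, any 1 young Trp53KO or any 1 old Trp53KO library but 2444 (0.0501 to 0.0676). With PTENKO, Mt2 lost it without 2421, 2426, 2435 or 2441 (0.0545 to 0.556), Gsta2 and Lepr without 2421 or 2441, Gpnmb without 2421 or 2426, Mx2 without 2426 or 2429, Gvin1 without 2441 and Cbr3 without 2421 (0.0505 to 0.0548). Cdkn1a with Trp53KO lost it without 2460 (0.0507), and Lepr without 2435 (0.142). Values moved far as well: Mt1 and Lepr with Trp53KO were 1.07 and -0.96, and Mt2 and Lepr with PTENKO -0.58 and -1.74, without library 2435.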

How the results depend on the processing

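Library-size scaling and the overlap of age changes without 2435 were chosen after seeing the data. So were fits without 2435 and 2460, or without 2435 where a comparison does not use it. The counts of called genes were 1214 for age in Rosa26KO, 4999 for age in Trp53KO, 43 for age in PTENKO, 410 for young Trp53KO, 3212 for old Trp53KO, 3608 for young PTENKO, 926 for old PTENKO, 1055 for Trp53KO over both ages, 3238 for PTENKO over both ages, 2378 for the Trp53KO interaction and 648 for the PTENKO interaction. With RLE factors all 11 counts stayed within 1.5 times of these, all 274 tested values of named genes kept direction and side, and all 89 list tests did. DESeq2 kept all 261 values of named genes tested, and voom kept 255, with 16 past the threshold no longer and 3 reversed. Of the 89 list tests, 75 held under fry, and 6 with an estimated correlation between genes. Leaving out 1 library kept 3260 of the values of named genes, with 162 no longer past the threshold and 6 reversed, and 1126 of the list tests, with 3 no longer past it. Where a count or a value moved, the cause was not tested, except that a fold minimum asks for more and that fewer genes or libraries enter a fit. With 5 libraries per group, each group mean rests on few animals, and genes with few counts are least well measured. No paired analysis was possible because the groups share no library number.

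Counts that moved by more than 1.5 times were, with a mean of at least 5 CPM, 736 for age in Rosa26KO, 13 for age in PTENKO and 2398 for young PTENKO. A fold minimum of 1.2 gave 139 for age in Rosa26KO, 2441 for age in Trp53KO, 16 for age in PTENKO, 89 for young Trp53KO, 781 for old Trp53KO, 1372 for young PTENKO, 187 for old PTENKO, 75 for Trp53KO over both ages, 892 for PTENKO over both ages, 901 for the Trp53KO interaction and 34 for the PTENKO interaction. With only the compared groups in the fit they were 5 for age in Rosa26KO, 153 for age in PTENKO, 1483 for young Trp53KO, 149 for old Trp53KO, 89 for old PTENKO, 435 for Trp53KO over both ages, 1345 for the Trp53KO interaction and 287 for the PTENKO interaction. The knockout percentage as covariate gave 75 for age in PTENKO. No low-count filter gave 394 for the PTENKO interaction, and library-size scaling 390 for the PTENKO interaction. DESeq2 gave 131 for age in PTENKO, 654 for young Trp53KO and 1115 for the PTENKO interaction. Voom with quality weights gave 395 for age in PTENKO, 2157 for young Trp53KO, 5735 for old Trp53KO, 6004 for young PTENKO, 2264 for old PTENKO, 4616 for Trp53KO over both ages, 5831 for PTENKO over both ages, 4282 for the Trp53KO interaction and 1191 for the PTENKO interaction. Without both 2435 and 2460 they were 6015 for old Trp53KO, 3891 for Trp53KO over both ages and 4685 for the Trp53KO interaction. At an unadjusted p under 0.01, 42 genes changed the same way and 52 in opposite directions with age in Rosa26KO and PTENKO, and 191 and 20 in Trp53KO and PTENKO. Without library 2435, 174 changed the same way in Rosa26KO and Trp53KO, 23 in Rosa26KO and PTENKO and 89 in Trp53KO and PTENKO.

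Leaving out 1 library at a time, the counts ranged from 296 to 1529 for age in Rosa26KO, 4160 to 6263 for age in Trp53KO, 13 to 139 for age in PTENKO, 169 to 1177 for young Trp53KO, 2123 to 5263 for old Trp53KO, 2086 to 5033 for young PTENKO, 364 to 1232 for old PTENKO, 631 to 3022 for Trp53KO over both ages, 2475 to 4718 for PTENKO over both ages, 1486 to 3905 for the Trp53KO interaction and 132 to 931 for the PTENKO interaction. The log2 change of Trp53 ranged from -0.145 to 0.065 for age in Rosa26KO, 0.609 to 0.739 for age in Trp53KO, -0.185 to -0.024 for age in PTENKO, -1.087 to -1.002 for young Trp53KO, -0.439 to -0.230 for old Trp53KO, 0.091 to 0.216 for young PTENKO, 0.002 to 0.211 for old PTENKO, -0.743 to -0.638 for Trp53KO over both ages, 0.083 to 0.187 for PTENKO over both ages, 0.609 to 0.817 for the Trp53KO interaction and -0.163 to 0.047 for the PTENKO interaction. That of Pten ranged from 0.044 to 0.197 for age in Rosa26KO, -0.650 to -0.512 for age in Trp53KO, 0.088 to 0.237 for age in PTENKO, 0.058 to 0.179 for young Trp53KO, -0.637 to -0.494 for old Trp53KO, -1.479 to -1.357 for young PTENKO, -1.445 to -1.286 for old PTENKO, -0.253 to -0.182 for Trp53KO over both ages, -1.428 to -1.346 for PTENKO over both ages, -0.767 to -0.609 for the Trp53KO interaction and -0.039 to 0.120 for the PTENKO interaction. Genes tracking the knockout percentage numbered 0 in every fit for Trp53KO (edgeR, the tool run for this, with 409 genes at an unadjusted p under 0.05 in all 10 libraries), 0 to 611 for PTENKO and 0 to 3561 for Rosa26KO.

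With voom, Trp53 changed by 0.055 with age in Rosa26KO and by -0.417 in old Trp53KO, and Pten by -0.261 in Trp53KO over both ages. Without 2435 and 2460 the last 2 were -0.372 and -0.246, and these 4 values of the Trp53KO comparisons passed the threshold. Reversed values with voom were -0.224 for Cyp3a41a and -0.128 for Cyp3a16 with age in Trp53KO, and 1.152 for the Trp53KO interaction of Mt1. With 1 library left out, the values ran from -0.002 to 5.870 for Mt1 and from -0.145 to 6.790 for Mt2 with age in Rosa26KO and from -4.806 to 1.067 for the Trp53KO interaction of Mt1, reversed only without the library labelled old Rosa26KO 2435 (-0.002, -0.145 and 1.067). They ran from -0.825 to 5.522 for Cyp3a41a and from -0.652 to 5.782 for Cyp3a16 with age in Trp53KO and from -0.273 to 6.135 for the Trp53KO interaction of Cyp3a41b, reversed only without old Trp53KO 2460. Without both, the interaction was -0.395 for Cyp3a41b and 1.246 for Mt1.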

Other observations

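The lists, genes and values in this part were chosen after seeing the results. Old Trp53KO livers had higher genes of senescence, of resident macrophages and of the immediate early response than young ones. Of 26 genes of senescence and its secreted factors, 20 rose and 1 fell (21 and 1 adjusted over the list alone, median 1.35, camera adjusted p = 4.41e-08, and adjusted p = 0.102 with an estimated correlation). Macrophage and Kupffer cell markers rose in 11 of 20 cases and fell in 1 (14 and 1 adjusted over the list alone, median 0.96, camera adjusted p = 2.59e-05, and adjusted p = 0.368 with an estimated correlation). The lysozyme gene Lyz2, expressed in macrophages, rose from 36.1 ± 3.66 to 132 ± 38.3 CPM, a log2 change of 1.87 ± 0.20. Among 22 immediate early genes, 11 rose and 0 fell (12 adjusted over the list alone, median 0.58, camera adjusted p = 0.0003, and adjusted p = 0.28 with an estimated correlation), with a median of 0.94 without young Trp53KO 2442. Ier5, an immediate early gene, rose from 5.62 ± 0.869 to 15.2 ± 3.35 CPM (1.43 ± 0.17).

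Over both ages, PTENKO livers had lower periportal genes and higher monocyte markers than Rosa26KO livers. Periportal genes fell in 11 of 20 cases and rose in 3 (12 and 3 adjusted over the list alone, median -0.60, camera adjusted p = 0.00477, and adjusted p = 0.215 with an estimated correlation). The urea cycle gene Cps1 fell by 1.35 ± 0.17 and the glutaminase gene Gls2, whose exons overlap Spryd4, by 0.96 ± 0.14. Infiltrating monocyte and macrophage markers rose in 12 of 18 cases and fell in 0 (12 adjusted over the list alone, median 1.17, camera adjusted p = 3.02e-10, and adjusted p = 0.161 with an estimated correlation).

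The ribosomal RNA gene Rn45s took 2.77% of the counts in old PTENKO 2432 and 0.29% to 0.71% in the other libraries.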
